A study of Mus musculus with 4 samples.

How the data were processed

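RNA sequencing was done on PanIN cells, the cells of pancreatic intraepithelial neoplasia, a precursor lesion of pancreatic cancer. Per the labels, living CD133-positive ductal epithelial cells were sorted from the pancreas of mice of a B6/129 hybrid background that carried KrasG12D and Pdx1-Cre. The mice were either p53+/+ or p53-/-, with 2 libraries per genotype. RNA was isolated with a PicoPure kit, and each library held the RNA of 2 mice of 1 genotype combined. Libraries were made with a TruSeq Stranded kit. The 2 libraries of a genotype are labelled as replicates, and each held other RNA than the next. A p-value therefore measures the spread between pools of 2 mice. By Xist and Y-linked counts the p53+/+ pools also differed in sex, which that spread includes. The type of p53-/- allele was not given in the sources used here. Below, p53+/+ and p53-/- cells stand for all cells in the libraries from mice of that genotype. Whether cells of other types in the p53-/- libraries lacked p53 was not tested.

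The authors deposited whole-number read counts per gene symbol, not normalized, in 1 table per library. STAR, CASAVA 1.8 and DESeq2 and the genome build mm10 are named per the submitters' processing notes, without their roles. The read counter, the annotation version and the strand setting of the counting were not given in the sources used here, so how reads of overlapping and antisense genes were shared out is unknown. Each table listed 23420 genes and ended with lines for reads in no gene and for ambiguous reads, which were left out of library sizes and tests. Reads in no gene made up 12.5% and 13.4% of the counts in p53+/+ libraries 1 and 2, and 13.5% and 13.1% in p53-/- libraries 1 and 2. Ambiguous reads made up 0.744% and 0.778%, and 0.729% and 0.679%, in the same order. Mitochondrially encoded genes were not analysed here, since no symbol of that list matched.

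The counts of genes summed to 56959734 and 73424375 in p53+/+ libraries 1 and 2, and to 69283987 and 81243780 in p53-/- libraries 1 and 2. A count of 3, the floor used here for a gene that was not detected, corresponded to 0.0527, 0.0409, 0.0433 and 0.0369 CPM, the scaled unit of edgeR, in that order. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was 1 library deposited again. Over genes with a summed count of at least 10, the chi-square statistic per degree of freedom was 261 between the p53+/+ libraries and 188.4 between the p53-/- libraries. It was 300.1 to 392.2 between libraries of different genotypes. Spearman's correlation across genes, which are not independent replicates, was 0.974 and 0.988 for the pairs within a genotype. Between genotypes it was 0.9625 to 0.974, so p53+/+ library 1 correlated as well with p53-/- library 1 as with p53+/+ library 2. The biological coefficient of variation was 27.5% over both genotypes, 32% for the p53+/+ pair alone and 22.2% for the p53-/- pair alone.

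Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter (15646 genes kept) and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Only the genotype entered the model. Each log2 fold change is p53-/- minus p53+/+ as estimated by edgeR, with a standard error (SE) taken from the change and the F statistic. CPM values are TMM-scaled and are given as mean ± SD of 2 libraries. DESeq2 1.42.0 with default settings was the planned second tool, and limma 3.58.1 (voom) the third. Gene coordinates are 1-based on GRCm38 (mm10), from GENCODE M21, which had no unique entry for 988 of the tested symbols.

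Before the data were examined, 30 gene lists with 613 symbols were fixed (594 were in the tables, 11 of them under an older name). They covered p53 targets, Yap/TEAD targets, the Hippo pathway, cell cycle, epithelial programs, signalling outputs, sex-linked genes and markers of other cell types that a sorted pancreatic fraction could hold. Lists with at least 5 tested members, 28 of them, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry were run beside it. The estimated correlation rested on 2 residual degrees of freedom, so that setting had little power to call a list. A list that did not pass there is not shown to be unchanged. Counts of members are given from the adjustment over all genes tested and "adjusted over the list alone".

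The genes named were fixed by a rule before the data were examined: Trp53 and Ptpn14; the 12 genes with the largest change in each direction among those called, with at least 5 CPM in the higher genotype and separate ranges; from each list up to 3 called members with the smallest p per direction, or, with none called, the 2 members with the highest mean CPM; and the 3 most abundant members of each list of another cell type. Since edgeR called no gene, the parts that need calls were also applied to the calls of DESeq2. This, and a further condition, were chosen after seeing the data: the gene had to be called in the same direction in each of the 4 DESeq2 fits that left out 1 library. Such calls are termed kept. Changes and adjusted p given for single genes without 1 library are from these DESeq2 fits, and those of lists from edgeR and camera. In these fits the lone library of a genotype is assumed to vary like the pair of the other. Other genes named beside these were chosen after their values were seen: members given as examples of a count and the genes of the closing section.

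Alternatives planned before the data were examined were RLE, upper-quartile and library-size scaling, no low-count filter, a filter of at least 1 CPM in 2 samples, robust quasi-likelihood fitting, the replicate number as a block, removal of the genes of other cell types, limma-voom, DESeq2, an estimated correlation in camera, stricter thresholds and leaving out each library. The labels give the same replicate numbers to both genotypes but state no pairing.

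The whole procedure was tested on simulated counts for this comparison, with 15646 genes of which 200 were changed. For genes changed 2-, 4-, 8- and 16-fold, edgeR recovered 14%, 56%, 76% and 78%, and DESeq2 recovered 52%, 86%, 92% and 96%. The edgeR rates did not carry over to the real data. There H19 (log2 change 4.99, SE 0.288) and Gpnmb (3.52, SE 0.221) both had an edgeR adjusted p of 0.138. That edgeR called 0 real genes therefore does not show that such large changes were absent. Among unchanged genes edgeR made 6 false calls and DESeq2 made 197. With nothing changed, edgeR called 0 genes, with 4.75% at an unadjusted p under 0.05, and DESeq2 called 176. The 95% intervals held the true change for 95.2% of genes. A simulated list shifted by 0.8 on the log2 scale had a camera p of 5.31e-28, or 0.00641 with an estimated correlation, and unshifted lists had 0.378 and 0.699. Simulated genes varied independently, whereas the correlation estimated within the real lists ran from -0.0537 (sex-linked genes) to 0.956 (G2/M genes). The simulation therefore does not test the preset correlation of 0.01 on lists whose members move together.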

Results

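PanIN cells of p53+/+ and p53-/- mice were compared by RNA sequencing, with 2 libraries per genotype and the pooled RNA of 2 mice in each. All mice carried KrasG12D and Pdx1-Cre, which places the mutant Kras in the pancreatic epithelium. The libraries held 56959734 and 73424375 gene counts for p53+/+ and 69283987 and 81243780 for p53-/-, in which 17656 to 17927 genes had any count. The study asked which genes differ in expression when p53 is absent, and its title names an axis from p53 through Ptpn14, a phosphatase, to Yap, the transcriptional coactivator of the Hippo pathway.

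Loss of p53 was visible in its own transcript. Trp53 (chromosome 11, 69580359 to 69591873) stood at 76.4 ± 2.44 CPM (SD, n = 2) in p53+/+ cells and 30.5 ± 0.815 CPM in p53-/- cells, a log2 change of -1.33 (SE 0.0878, 95% interval -1.57 to -1.09). All 4 libraries followed their labels, with 74.7 and 78.1 CPM against 31.0 and 29.9 CPM. The edgeR adjusted p was 0.138 and that of DESeq2 6.96e-21. Reads from an allele that still makes part of the transcript would count here as well. The type of allele is not given, and the source of the remaining reads, other cell types in the libraries included, was not tested. The remaining level therefore does not measure functional p53 RNA.

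Across the transcriptome, 1017 genes were called higher and 786 lower in p53-/- cells by DESeq2, and 144 and 94 of these calls were kept whichever library was left out. The edgeR test called 0 genes in either direction, with a smallest adjusted p of 0.138; at an unadjusted p under 0.05 it counted 1824 higher and 1485 lower genes, against 782 in all by chance. Limma-voom called 0 as well. The ranges of the genotypes were separate for 57.5% of tested genes, where chance gives 33.3%. On simulated data without any change DESeq2 made 176 calls and edgeR 0, so single DESeq2 calls near the threshold are the less secure ones. Leaving out p53-/- library 2 lowered the DESeq2 counts most, to 242 higher and 183 lower genes. They were 392 and 493 without p53-/- library 1, 567 and 504 without p53+/+ library 2, and 950 and 538 without p53+/+ library 1.

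The 12 kept calls with the largest increase in p53-/- cells, among genes with at least 5 CPM, included 5 collagen genes. H19, a fetal non-coding RNA (chromosome 7, 142575529 to 142578143), rose from 0.261 ± 0.00518 to 8.35 ± 1.57 CPM, a log2 change of 4.99 (SE 0.288; DESeq2 adjusted p = 1.74e-32). Saa3, an acute-phase protein, followed with 4.49 (SE 0.374; 1.47e-33), and Tnc, the matrix protein tenascin C, with 4.02 (SE 0.439; 4.1e-20). Next came Col1a2 (3.83), Slfn4 (3.81), Col1a1 (3.80), Cdkn2a (3.56), Sox11 (3.55), Col6a3 (3.54), Gpnmb (3.52), Col3a1 (3.52) and Col5a2 (3.42), whose DESeq2 adjusted p ranged up to 7.64e-13. Without p53-/- library 2 the change of Tnc was 3.4, and without p53-/- library 1 those of Col1a2 and Col1a1 were 3.21 and 3.01. The edgeR adjusted p of these 12 genes lay between 0.138 and 0.143.

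Of the 12 kept calls with the largest decrease in p53-/- cells, among genes with at least 5 CPM, 7 are genes of B cells or dendritic cells. They were Igj (log2 change -4.21), Tnfrsf13c (-3.35), Ms4a1 (-3.29), Cd19 (-3.15) and Cd79a (-3.13) of the B lineage, and Clec9a (-3.52) and Flt3 (-3.13) of dendritic cells. Flt3 fell from 25.4 ± 1.69 to 2.90 ± 0.483 CPM (DESeq2 adjusted p = 1.68e-38). The others were Nlrp1c-ps (-4.88), a pseudogene 1.66 Mb from Trp53 with the close relatives Nlrp1a and Nlrp1b beside it, Adcy5 (-4.22), an adenylyl cyclase, Sept3 (-3.51), Adamts16 (-3.32) and Ceacam20 (-3.14). The largest DESeq2 adjusted p of the 12 was 3.65e-05, and their edgeR adjusted p lay between 0.138 and 0.171. The B-lineage genes were higher in p53+/+ library 2, and without it the changes of Igj, Tnfrsf13c, Ms4a1, Cd19 and Cd79a were -3.30, -2.16, -2.06, -2.18 and -2.14. Without p53+/+ library 1, those of Tnfrsf13c and Ms4a1 were -3.98 and -3.94, and without p53-/- library 2 that of Nlrp1c-ps was -5.73.

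Of 45 measured p53 targets, 5 were called lower and 3 higher by DESeq2, and the 3 kept calls were all lower. Eda2r, a death receptor of the tumor necrosis factor family, fell from 86 and 95 counts to 4 and 3 counts, a ratio of 29.7 (counting interval 14.1 to 74.9; DESeq2 adjusted p = 7.99e-08). Ephx1, the microsomal epoxide hydrolase, fell from 178 ± 3.97 to 53.8 ± 17.4 CPM, and Btg2, an antiproliferative gene, from 1566 ± 106 to 779.9 ± 99.2 CPM. Their log2 changes were -1.73 (SE 0.256) and -1.01 (SE 0.169), with DESeq2 adjusted p = 9.72e-08 and 4.28e-07. The calls of Ccng1 (-0.42) and Psrc1 (-0.81) ended without any 1 of the libraries, while their changes stayed at -0.43 to -0.40 and -0.83 to -0.77. Cdkn1a, the cell cycle inhibitor p21 and the best known target, stood at 370 and 430 CPM against 338 and 298 CPM (log2 change -0.33, SE 0.14; DESeq2 adjusted p = 0.208).

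Against this direction, Mdm2, which encodes the ubiquitin ligase of p53, was called higher by DESeq2 at 101 ± 0.266 and 140.2 ± 0.335 CPM (0.48, SE 0.0853; adjusted p = 0.00126), as were Plk2 (0.50) and Sulf2 (0.41). Each of these 3 calls ended when a library was left out: Mdm2 and Sulf2 without any 1 of the 4, and Plk2 without p53+/+ library 2 or either p53-/- library. The changes of Mdm2 and Sulf2 hardly moved in these fits, at 0.48 to 0.49 and 0.36 to 0.47. The list as a whole had a median log2 change of -0.18 with 32 of 45 members negative, and camera placed it lower (adjusted p = 0.0155). With an estimated correlation its adjusted p = 0.548. By edgeR 0 members were called over all genes and 1 lower member adjusted over the list alone, with 3 higher and 8 lower at an unadjusted p under 0.05; DESeq2 gave the same 3 and 5 adjusted over the list alone. The shares of other cell types differed between the same libraries (list medians of 2.22 for fibroblasts, 0.42 for macrophages and -0.71 for lymphocytes), and their p53 targets were not separated.

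**Figure D1:**
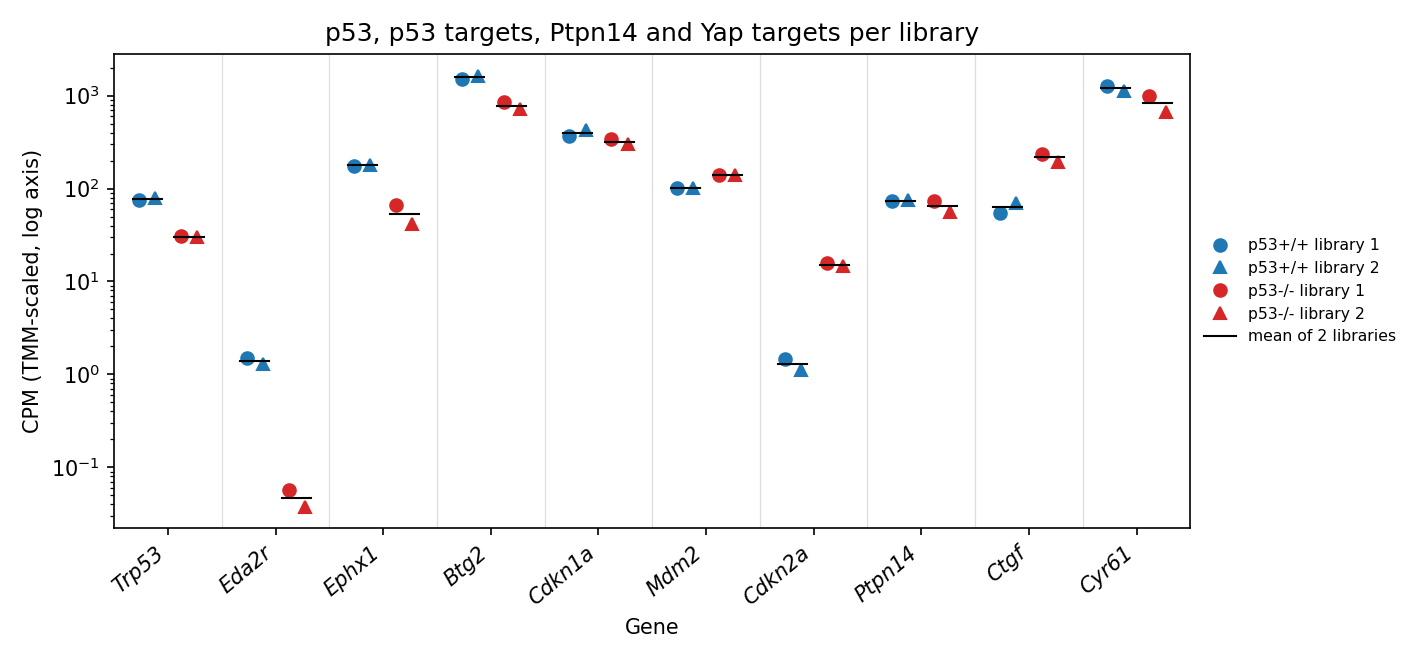
TMM-scaled CPM (log axis) of 10 genes in each of the 2 p53+/+ libraries (blue) and 2 p53-/- libraries (red), with the mean of each genotype as a black line. Trp53, Eda2r, Ephx1 and Btg2 lay lower and Cdkn2a, Mdm2 and Ctgf higher in both p53-/- libraries, while Ptpn14 was lower in p53-/- library 2 alone (55.2 against 72.6 to 75.8 CPM).

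Ptpn14 (chromosome 1, 189728268 to 189876695) was not called by either tool, of which edgeR did not call Trp53 either (adjusted p = 0.138). It stood at 72.6 and 75.8 CPM in p53+/+ cells and at 73.6 and 55.2 CPM in p53-/- cells (log2 change -0.20, SE 0.167, 95% interval -0.66 to 0.25; adjusted p = 0.516 by edgeR and 0.632 by DESeq2). The lower value came from p53-/- library 2, and without it the change by DESeq2 was -0.01, against -0.41 without p53-/- library 1. A decrease below -0.66 on the log2 scale lay outside the interval, for the mixed cells of these libraries. Their make-up differed: the fibroblast list had a median of 2.22, and Epcam stood at 503 and 212 against 387 and 330 CPM. Ptpn14 reads of PanIN cells were not separated from those of other cells, so a change within PanIN cells was not tested.

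Among 25 measured Yap/TEAD targets, 2 rose and 0 fell by DESeq2, and both calls were kept. Ctgf, a secreted matricellular protein and standard Yap target, went from 62.7 ± 10.7 to 216 ± 30.8 CPM (1.78, SE 0.186; DESeq2 adjusted p = 9.33e-14), and Ccdc80 from 4.97 ± 1.73 to 26.5 ± 12.2 CPM (2.41, SE 0.459; 4.61e-06). Cyr61, the other standard target, lay the other way at 1272 and 1130 against 979 and 671 CPM (-0.54, SE 0.237; DESeq2 adjusted p = 0.161), and Axl stood at 288 and 485 against 608 and 485 CPM. The median of the list was 0.12, and camera did not call it (adjusted p = 0.443, and 0.744 with an estimated correlation). Without p53+/+ library 1 the median was 0.20, and without p53-/- library 1 it was 0.058, with adjusted p = 0.106 to 0.839 over the 4 fits without 1 library. The edgeR test passed 0 members over all genes, with 3 higher and 2 lower at an unadjusted p under 0.05, and 1 higher passed adjusted over the list alone; DESeq2 called 2 higher adjusted over the list alone. Ctgf and Ccdc80 are abundant in fibroblasts as well, whose markers were higher in both p53-/- libraries.

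Of 25 Hippo pathway components, DESeq2 called Tead2, a DNA-binding partner of Yap (0.77), and Mob1b (0.51) higher and none lower, while edgeR called 0 members over all genes or adjusted over the list alone, with 4 higher and 2 lower at an unadjusted p under 0.05. DESeq2 called 3 higher and 2 lower adjusted over the list alone. Both calls ended when a library was left out, Tead2 without p53+/+ library 2 (adjusted p = 0.0657) or p53-/- library 1 or 2 (0.23 and 0.0893), and Mob1b without any 1 of the 4 (0.293 to 0.734). Wwc1 and Amotl2, its most abundant members, had log2 changes of -0.52 (SE 0.24) and -0.68 (SE 0.209), with DESeq2 adjusted p = 0.237 and 0.0514. The list had a median of 0.09 and was not called (camera adjusted p = 0.347, 0.744 with an estimated correlation). Its median was 0.18 without p53+/+ library 1, 0.15 without p53-/- library 2 and 0.029 without p53-/- library 1, where the test pointed lower (0.839).

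Cell cycle transcripts lay higher in p53-/- cells. All 30 G2/M genes and 28 of 30 S phase genes had a positive log2 change, with medians of 0.78 and 0.71 (camera adjusted p = 8.36e-10 and 1.84e-10). At an estimated correlation both had an adjusted p = 0.548. DESeq2 called 10 G2/M genes and 16 S phase genes higher and 0 lower, or 23 and 22 adjusted over the list alone, and no call was kept. As for edgeR, 0 members passed over all genes, with 18 and 20 higher at an unadjusted p under 0.05, and 0 and 18 passed adjusted over the list alone. Mki67, the proliferation marker Ki-67, stood at 163 ± 19.2 and 298 ± 53.2 CPM (0.87, SE 0.18; DESeq2 adjusted p = 0.00144), and Mcm6, a subunit of the replicative helicase, at 71.3 ± 2.21 and 141 ± 28.6 CPM (0.99, SE 0.17; 0.00023). Top2a and Mcm3, called too, had changes of 0.83 and 0.58, and Pcna, not called, 0.37. The fibroblast and macrophage lists lay higher in the same libraries (medians 2.22 and 0.42), and cycling cells of each type were not separated.

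The rise was larger in p53-/- library 2: Mki67 stood at 260.1 and 335 CPM, and the summed CPM of the G2/M list was 748 and 840.1 in p53+/+ against 1073 and 1581 in p53-/- libraries 1 and 2. Without that library the medians of the G2/M and S phase lists were 0.35 and 0.40. The DESeq2 adjusted p without it of Mki67 was 0.237, of Mcm6 0.0927, of Top2a 0.684 and of Mcm3 0.865. Without p53+/+ library 1 the calls of Top2a (0.128) and Mcm3 (0.192) ended, and without p53+/+ library 2 that of Mcm3 (0.141).

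Markers of the ductal epithelium were abundant in all libraries and moved little as a group. Clu and Spp1 stood at 8060 and 4324, and 4105 and 3553 CPM in p53+/+ cells, against 8759 and 7700.1, and 4851 and 2816 CPM in p53-/- cells. Of 24 members DESeq2 called Onecut1, a ductal transcription factor, lower (-1.35, SE 0.264; adjusted p = 0.000353), which was kept. Hnf1b (-1.01) was called lower and Krt7 (1.27) higher. The call of Hnf1b ended without p53-/- library 2 (0.247), and that of Krt7 without either p53-/- library (0.165 and 0.166), its change being 1.87 without p53+/+ library 1. The list's median was -0.22 (camera adjusted p = 0.191; 0.744 with an estimated correlation). Its test depended on the p53+/+ libraries: without library 1 it was higher in p53-/- cells (adjusted p = 0.0255, median 0.28) and without library 2 lower (5.84e-06, median -0.55), as it was without p53-/- library 1 (0.01). By edgeR 0 members were called, over all genes or adjusted over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05; DESeq2 gave 1 and 2 adjusted over the list alone.

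Genes of gastric-type metaplasia and PanIN, which mark the conversion of pancreatic epithelium towards a stomach-like mucous state, had a median of 0.79 over 25 members (camera adjusted p = 5.35e-04). With an estimated correlation the adjusted p = 0.548, and without p53+/+ library 2 it was 0.47. The median was 1.87 and 0.37 without p53+/+ library 1 and 2. DESeq2 called 8 higher and 1 lower, and kept Dclk1, a tuft cell kinase (6.23 ± 1.48 to 25.0 ± 2.79 CPM; 2.00, SE 0.231; adjusted p = 7.92e-11), and Agr2, a mucus-folding protein (1.42, SE 0.233; 1.16e-05). Gkn3 (3.15) and the gastric mucin Muc6 (2.85) were called but not kept, since without p53+/+ library 1 their adjusted p was 0.151 and 0.18; without p53-/- library 1 their changes were 2.23 and 2.00, and without p53+/+ library 2 3.86 and 3.44. By edgeR 0 members passed over all genes and 2 higher adjusted over the list alone (9 higher and 1 lower at an unadjusted p under 0.05); DESeq2 called 10 higher and 1 lower adjusted over the list alone. The most abundant members, Dmbt1 and Lcn2, varied widely between the p53+/+ libraries, at 11175 and 689 CPM and at 592 and 81.4 CPM, against 2954 and 7078, and 280.2 and 383 CPM in p53-/- cells.

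Acinar transcripts, the digestive enzymes of the exocrine pancreas, were present in every library. Ctrb1 stood at 8674 and 4621 CPM in p53+/+ and 3312 and 8928 CPM in p53-/- cells, with Prss2 at 5711, 2510.2, 1246 and 4507 CPM and Pnlip at 5902, 3256, 321 and 2902 CPM in that order. The list was lower (median -0.56, camera adjusted p = 0.021; 0.744 with an estimated correlation). That call ended without p53+/+ library 1 (0.971) and without p53-/- library 1 (0.917), the library with the fewest acinar reads. The median without p53+/+ library 1 and 2 was -0.062 and -1.02, and without p53-/- library 1 and 2 0.0076 and -1.87. DESeq2 called 2 of 32 members lower, Clps (-1.50) and Amy1 (-1.37), and edgeR called 0 over all genes or adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05. Without p53+/+ library 1 their DESeq2 adjusted p was 0.648 and 0.393 and without p53-/- library 1 0.139 and 0.372. Without p53+/+ library 2 that of Clps was 0.53, and without p53-/- library 2 its change was -2.47 and the adjusted p of Amy1 0.212; without p53+/+ library 1 the change of Amy1 was -0.70. DESeq2 called 0 members adjusted over the list alone.

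Endocrine genes were not called as a list (median -0.27 over 20 members, camera adjusted p = 0.272; 0.744 with an estimated correlation), but passed, lower, without p53+/+ library 1 (0.00214). The median was -0.47 and -0.075 without p53+/+ library 1 and 2, and -0.97 without p53-/- library 1. DESeq2 called Ghrl, the ghrelin gene, higher and kept it (0.863 and 0.636 against 4.69 and 11.3 CPM; 3.42, SE 0.556; adjusted p = 1.12e-07; 2.65 without p53-/- library 2). It also called Cpe (1.07) higher and Sst (-2.27) lower, 3 higher and 3 lower adjusted over the list alone. Cpe was not called without p53+/+ library 1 (0.0893) or p53-/- library 2 (0.591). Sst was not called without p53-/- library 2 (0.0776), with changes of -2.86 and -1.23 without p53+/+ library 1 and 2. Mafb, at 557 to 703 CPM, and Ppy, at 64.7 to 157 CPM, had changes of -0.09 and -0.82. The edgeR test passed 0 members by either adjustment, with 3 higher and 3 lower at an unadjusted p under 0.05.

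Intestinal and basal or squamous genes had few abundant members. The intestinal list (11 members, median 0.32) passed camera at an adjusted p = 0.0378, with 0.688 at an estimated correlation, and lost the call without p53+/+ library 2 (0.506, in the other direction) or p53-/- library 1 (0.232), with DESeq2 (0.24), with no low-count filter (0.0706) and with the filter of 1 CPM in 2 samples (0.108). Its median was 1.87 and -0.44 without p53+/+ library 1 and 2, and 0.096 without p53-/- library 2. DESeq2 called only Muc2, an intestinal mucin, higher (2.04), over all genes and adjusted over the list alone, and edgeR 0 with 3 higher at an unadjusted p under 0.05. Muc2 was not called without p53-/- library 1 (0.125) or 2 (0.393), and its change was 3.01 without p53+/+ library 1. Anpep stood at 205 to 235 CPM, Fcgbp at 234 and 28.8 against 69.0 and 78.3 CPM, and Vil1 at 78.4 and 14.1 against 55.1 and 60.3 CPM. The basal list (10 members, median 1.60) passed at an adjusted p = 0.0172, with 0.548 at an estimated correlation and 0.132 without p53+/+ library 2, where its median was 0.70. That median was 3.17 without p53+/+ library 1 and 0.89 without p53-/- library 2, and the filter of 1 CPM in 2 samples ended the call (0.0759). DESeq2 kept Krt17, a stress keratin, lower (186 ± 31.8 to 87.9 ± 5.34 CPM; -1.08, SE 0.157; 8.1e-06) and Krt14 higher, from 0 and 2 counts to 138 and 116 counts. The ratio for Krt14 was 111 with a counting interval of 30.3 to 918. Ivl, also called higher (3.10), was not called without p53-/- library 2 (0.202), and Sprr1a stood at 13.4 and 1.31 against 13.9 and 13.8 CPM. Over all genes edgeR called 0 basal members (3 higher and 2 lower unadjusted) and 3 higher and 1 lower adjusted over the list alone, where DESeq2 called 5 and 1.

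**Figure D2:**
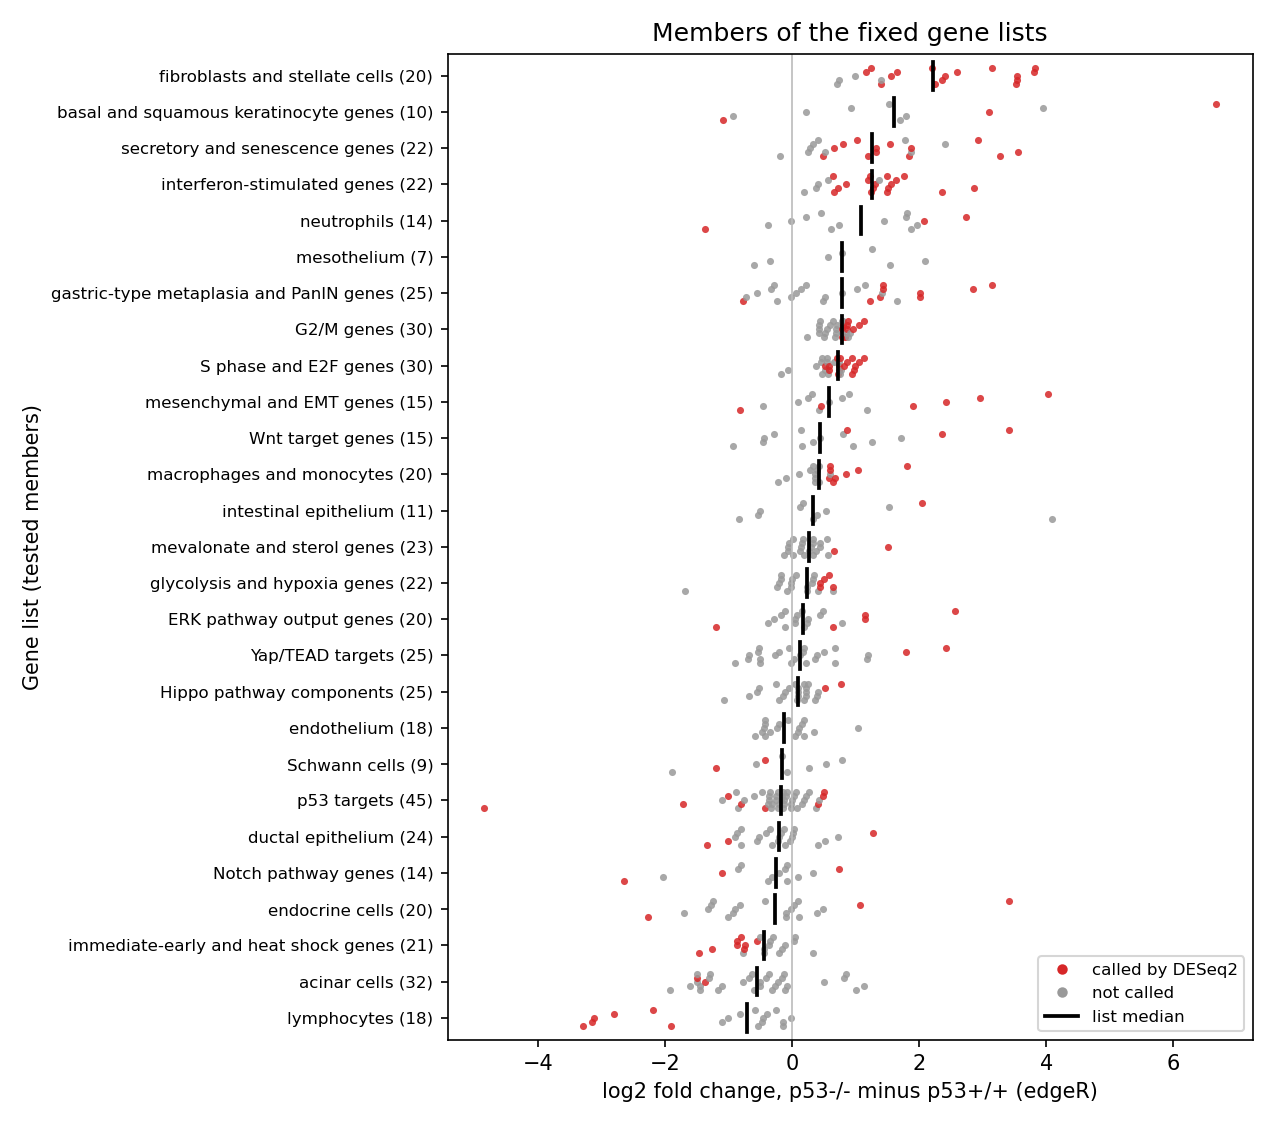
Log2 fold change (p53-/- minus p53+/+, edgeR) of each tested member of 27 gene lists, sorted by the list median (black line), with members called by DESeq2 in red. All 20 fibroblast genes and all 22 interferon-stimulated genes lie above 0, all 18 lymphocyte genes lie below 0, and the p53 and Yap/TEAD targets spread to both sides.

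Fibroblast and stellate cell genes made up the list with the largest median, 2.22 over 20 members, all positive (camera adjusted p = 2.19e-13). At an estimated correlation its adjusted p = 0.548. DESeq2 called 16 higher and 0 lower and kept 8, and 17 were called adjusted over the list alone. The edgeR test passed 0 over all genes, 17 had an unadjusted p under 0.05, and 16 passed adjusted over the list alone. Col3a1, a fibrillar collagen, went from 15.4 ± 3.08 to 176 ± 62.9 CPM (3.52, SE 0.339; DESeq2 adjusted p = 9.06e-23), Col1a2 from 6.41 ± 1.35 to 91.0 ± 45.5 CPM and Col6a3 from 1.37 ± 0.46 to 15.9 ± 6.28 CPM. Sparc, the most abundant member, stood at 88.4 and 82.8 against 239 and 142 CPM (1.15; adjusted p = 0.00323, and 0.0575 without p53-/- library 1). Pdgfra, a fibroblast receptor, had a change of 3.15 (2.54 without p53-/- library 2), and Acta2, the smooth muscle actin of activated stellate cells, 2.59, both kept. A sort for CD133-positive epithelial cells is meant to remove fibroblasts.

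Macrophage transcripts were among the most abundant in every library, although a sort of epithelial cells is meant to remove macrophages. Reads of other cells therefore remained after the sort. Prom1, the gene of CD133, stood at 296 and 114 CPM in p53+/+ and 137 and 141 CPM in p53-/- cells. The epithelial gene Epcam stood at 503 and 212 against 387 and 330 CPM, and the leukocyte gene Ptprc at 354 and 544 against 421 and 469 CPM. Lyz2 stood at 3741 and 7999 CPM in p53+/+ and 7778 and 7848 CPM in p53-/- cells, C1qb at 1320.4 and 1665 against 2143 and 2330.0 CPM, and Csf1r at 1310.3 and 1766 against 1913 and 1957 CPM. By camera the list was higher in p53-/- libraries (18 of 20 members positive, median 0.42, adjusted p = 1.0e-05, and 0.548 with an estimated correlation). Its median was 0.28 without p53+/+ library 1 and 0.72 without p53+/+ library 2, and 0.64 without p53-/- library 1. DESeq2 called 8 higher and 0 lower, over all genes and adjusted over the list alone. It kept Fcgr1, the high-affinity immunoglobulin receptor (48.4 ± 10.2 to 169 ± 41.3 CPM; 1.8, SE 0.253; adjusted p = 1.37e-08), and Ms4a7 (1.03, SE 0.103; 3.99e-10). The call of C1qb (0.58) ended without p53+/+ library 1 (0.149) or p53-/- library 1 (0.203) or 2 (0.644). Over all genes edgeR passed 0, 9 had an unadjusted p under 0.05, and 2 passed adjusted over the list alone.

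Lymphocyte genes went the other way as a list, although 6 of 18 members were called (median -0.71; camera adjusted p = 6.69e-04, and 0.596 with an estimated correlation). DESeq2 called 6 lower and 0 higher, over all genes and adjusted over the list alone, and kept 4. Cd19, the B cell coreceptor, stood at 19.8 and 57.3 against 4.26 and 4.44 CPM (-3.15, SE 0.582; adjusted p = 1.28e-07; -2.18 without p53+/+ library 2). Cd79a stood at 14.1 and 41.8 against 3.48 and 2.91 CPM (-2.14 without that library), Ms4a1 at a change of -3.29 (-2.06 without it, -3.94 without p53+/+ library 1), and Cd22 at 22.5 and 66.4 against 24.9 and 19.2 CPM. By edgeR 0 passed over all genes or adjusted over the list alone, with 6 lower at an unadjusted p under 0.05. Members such as Cd4 (-0.02), Cd3g (-0.15) and Zap70 (-0.14) hardly differed. The list's median was -0.34 without p53+/+ library 2, where camera still called it (0.0105), and -1.16 without p53+/+ library 1.

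Of the remaining markers, neutrophil genes had a median of 1.08 over 14 members (camera adjusted p = 0.021; 0.548 with an estimated correlation; 0.282 without p53+/+ library 2; 0.576 and a median of -0.10 without p53-/- library 1). The median was 2.03 without p53+/+ library 1 and 1.67 without p53-/- library 2. DESeq2 called Fpr1 (2.74) and Mmp8 (2.07) higher and Mmp9 (-1.37) lower, over all genes and adjusted over the list alone, and kept none of them. Fpr1 was not called without p53-/- library 2 (0.223), Mmp8 without p53-/- library 1 (0.157) or 2 (0.104), and Mmp9 without p53+/+ library 1 (0.0534) or p53-/- library 1 (0.104). The edgeR counts were 0 over all genes (2 higher and 1 lower unadjusted) and 2 higher adjusted over the list alone. Il1b stood at 702 to 1383 CPM with a change of 0.45, Ltf at 411 and 15.1 against 129 and 198 CPM, and Csf3r at 62.6 to 79.3 CPM with 0.22.

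Endothelial genes (18 members, median -0.13; camera adjusted p = 0.469, 0.843 with an estimated correlation) and mesothelial genes (7 members, 0.79; 0.12 and 0.548) had 0 calls by edgeR or DESeq2, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR counted 0 higher and 1 lower, and 1 higher and 0 lower. Without p53+/+ library 1 both passed, the endothelial list lower (0.00571) and the mesothelial list higher (0.0171), and the mesothelial list passed without p53-/- library 2 too (0.00762). The endothelial median was -0.48 and 0.32 without p53+/+ library 1 and 2, and -0.0048 and -0.28 without p53-/- library 1 and 2. The mesothelial median was 1.41 without p53+/+ library 2 and 1.26 without p53-/- library 2. Eng, Plvap and Ptprb had changes of -0.35, -0.47 and -0.06, and Krt19, Msln and Gpm6a of -0.36, 0.79 and -0.60. Krt19, a keratin that ductal cells express as well, stood at 925 and 247 CPM in p53+/+ against 443 and 472 CPM in p53-/- cells.

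Schwann cell genes (9 members, median -0.17; adjusted p = 0.402, 0.744 with an estimated correlation) had Mbp (-0.42) and Ngfr (-1.21) called lower by DESeq2, over all genes and adjusted over the list alone, and 0 by edgeR, with 0 higher and 2 lower unadjusted. The list's median was 0.29 and -0.35 without p53+/+ library 1 and 2, and -0.42 without p53-/- library 1. Neither call was kept: both ended without any 1 of the libraries, at adjusted p = 0.115 to 0.753 for Mbp and 0.0602 to 0.605 for Ngfr. Pmp22 and Erbb3 had changes of 0.27 and -0.17. Of the erythroid genes 2 were tested, too few for camera. Alas2 reached 3.84 CPM in p53-/- library 1 and stood at 0.0270 to 0.141 CPM in the others. DESeq2 called it (4.58; adjusted p = 0.0458), edgeR did not (0 at an unadjusted p under 0.05), and without p53-/- library 1 its change was 0.08. It was not called without p53+/+ library 2 (0.192) either, and its change was 6.18 and 5.55 without p53+/+ library 1 and p53-/- library 2. Klf1 stood at 0.108 to 0.194 CPM.

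**Figure D3:**
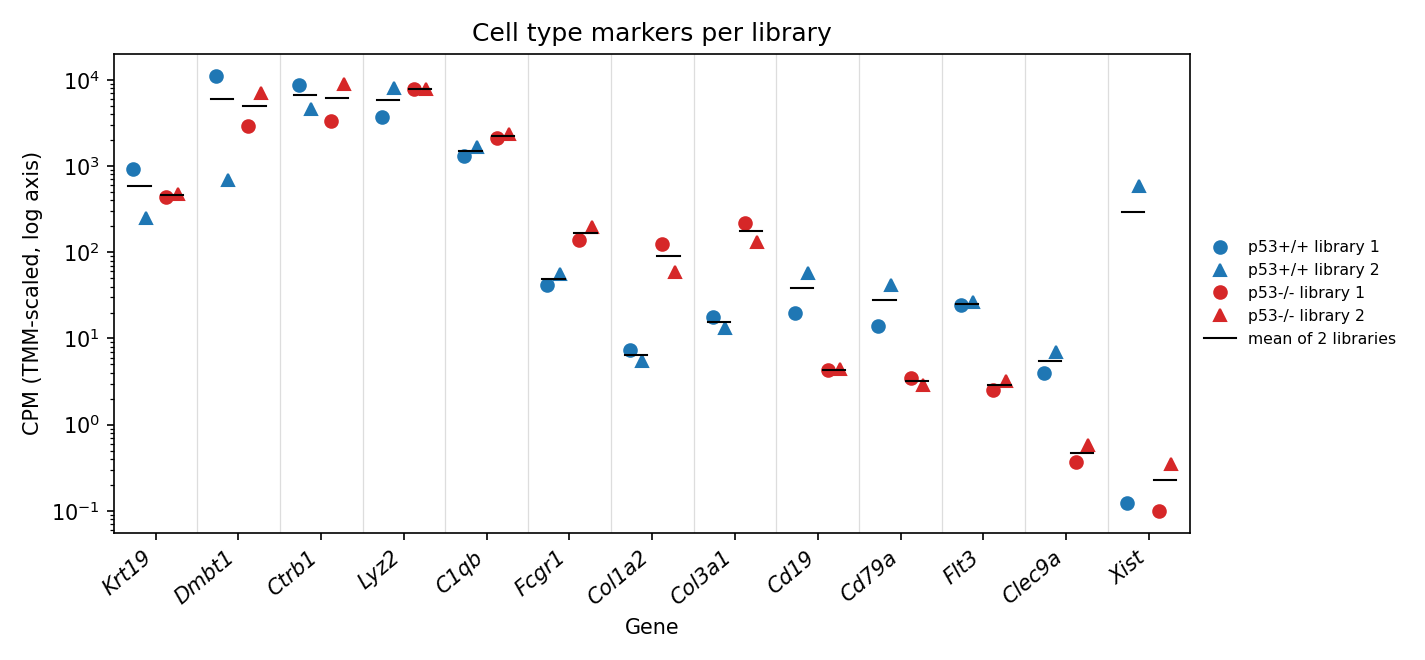
TMM-scaled CPM (log axis) of epithelial, acinar, macrophage, fibroblast, B cell and dendritic cell markers and Xist in each library (p53+/+ blue, p53-/- red, genotype mean as a black line). Col1a2 and Col3a1 lay higher and Cd19, Cd79a, Flt3 and Clec9a lower in both p53-/- libraries, and Xist was abundant (587 CPM) in p53+/+ library 2 alone.

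Interferon-stimulated genes were higher as a group in p53-/- cells, with all 22 members positive and a median of 1.25 (camera adjusted p = 1.05e-12). With an estimated correlation its adjusted p = 0.548. The macrophage and fibroblast lists lay higher in the same libraries (medians 0.42 and 2.22), and the cell type behind these reads was not separated. DESeq2 called 17 higher and 0 lower and kept 5, and 18 passed adjusted over the list alone. Kept examples were Ifi44 (13.1 ± 2.94 to 67.0 ± 11.8 CPM; 2.36, SE 0.232; adjusted p = 2.3e-15), Bst2, which tethers virions to cells (1.27, SE 0.149; 2.23e-08), and Ifit2, an inhibitor of viral translation (1.76, SE 0.261; 5.84e-07). By edgeR 0 passed over all genes, 18 had an unadjusted p under 0.05, and 14 passed adjusted over the list alone. Cxcl10 (0.73) and Parp14 (0.66), the most abundant members, were called but not kept: Cxcl10 ended without p53+/+ library 1 (0.0663) or 2 (0.167) or p53-/- library 1 (0.474), and Parp14 without p53+/+ library 2 (0.215) or p53-/- library 2 (0.805).

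Secretory and senescence genes had 21 of 22 members positive and a median of 1.26 (camera adjusted p = 8.81e-11; 0.548 with an estimated correlation). Fibroblasts and macrophages, whose lists lay higher too (medians 2.22 and 0.42), express several of these members. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the cell cycle inhibitor p16 and the Mdm2 inhibitor Arf, rose from 1.46 and 1.12 CPM to 15.8 and 14.7 CPM (3.56, SE 0.226; DESeq2 adjusted p = 1.04e-37). Il1a, an alarmin, went from 121 ± 34.8 to 435 ± 128 CPM (1.84, SE 0.32; 1.99e-06) and Csf2, the growth factor GM-CSF, from 0.848 ± 0.178 to 6.43 ± 2.88 CPM (2.92, SE 0.447; 2.63e-07). DESeq2 called 13 higher and 0 lower, or 18 adjusted over the list alone, and kept 4. The edgeR test passed 0 over all genes, 16 had an unadjusted p under 0.05, and 11 passed adjusted over the list alone. Cxcl2 (0.48) and Cxcl1 (1.02), the most abundant members, were not kept: Cxcl2 ended without any 1 of the libraries (0.117 to 0.462) and Cxcl1 without p53-/- library 1 (0.0639).

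Immediate-early and heat shock genes were lower, with 18 of 21 members negative and a median of -0.45 (camera adjusted p = 1.0e-05; 0.548 with an estimated correlation). DESeq2 called 8 lower and 0 higher, or 12 adjusted over the list alone, and kept the heat shock chaperone Hspa1b (471 ± 78.7 to 170 ± 67.4 CPM; -1.47, SE 0.333; adjusted p = 5.05e-04). Fos stood at 5320 and 5519 against 3903 and 3496 CPM (-0.55) and Zfp36 at 5093 and 6065 against 3138 and 3470 CPM (-0.76). Fos was not called without p53+/+ library 2 (0.0924) or p53-/- library 1 (0.0956) or 2 (0.533), and Zfp36 without p53-/- library 1 (0.129) or 2 (0.0627). By edgeR 0 passed over all genes or adjusted over the list alone, with 8 lower at an unadjusted p under 0.05. These genes also respond to tissue dissociation, the step before the sort.

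ERK output genes were not called as a list (20 members, median 0.16; camera adjusted p = 0.0701, and 0.673 with an estimated correlation; 0.0013 without p53+/+ library 1 and 0.0436 without p53-/- library 2). The median was 0.35 without p53+/+ library 1 and -0.051 without p53+/+ library 2 (0.802). With DESeq2 in place of edgeR the list passed (0.0232). DESeq2 called 4 higher and 1 lower, over all genes and adjusted over the list alone. It kept the growth factors Areg (27.4 ± 3.48 to 60.2 ± 2.3 CPM; 1.14, SE 0.128; adjusted p = 6.38e-08) and Ereg (1.56 ± 0.533 to 9.20 ± 1.2 CPM; 2.56, SE 0.333; 4.43e-10), while Ccnd1, cyclin D1, lay lower (434 and 328 against 191 and 139 CPM; -1.21; adjusted p = 2.6e-04, and 0.063 without p53-/- library 2). Hbegf had a change of 0.25. Over all genes edgeR passed 0 (4 higher and 1 lower unadjusted), and 4 and 1 adjusted over the list alone.

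Mesenchymal and EMT genes (15 members, median 0.58; camera adjusted p = 7.24e-04, 0.548 with an estimated correlation) had 5 members called higher and 1 lower by DESeq2, over all genes and adjusted over the list alone. Tnc (4.02, or 3.4 without p53-/- library 2) and the metalloprotease Mmp2 (1.92 ± 0.0757 to 14.9 ± 0.82 CPM; 2.96, SE 0.173; adjusted p = 1.01e-37) were kept, and both are products of fibroblasts, whose own list had a median of 2.22. Fn1 and Vim, the most abundant, had changes of 0.42 and 0.08, and S100a4, the member called lower, -0.82 (its highest adjusted p without 1 library was 0.231, so it was not kept). The edgeR count was 0 over all genes (5 higher and 1 lower unadjusted) and 5 and 1 adjusted over the list alone.

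Wnt targets (15 members, median 0.44; camera adjusted p = 0.0128, 0.548 with an estimated correlation) lost their call without p53+/+ library 1 (0.0749) or p53-/- library 1 (0.13). The median was 0.70 and 0.72 without p53+/+ library 1 and 2. Lgr5, a stem cell receptor, was kept by DESeq2 (0.701 ± 0.194 to 7.52 ± 3.25 CPM; 3.42, SE 0.462; adjusted p = 5.85e-10), 1 of 3 members called higher over all genes and adjusted over the list alone. Tnfrsf19 and Rnf43 had changes of -0.93 and -0.46. Of 14 Notch pathway genes (median -0.26; camera adjusted p = 0.0738, 0.548 with an estimated correlation) DESeq2 kept Dtx1 lower (19.9 ± 1.66 to 3.16 ± 0.718 CPM; -2.66, SE 0.232; adjusted p = 1.39e-20), called Notch3 lower (-1.10) and Jag1 higher (0.74) without keeping them, and called 3 lower and 1 higher adjusted over the list alone. The Notch list passed without p53+/+ library 1 (0.0373) or p53-/- library 1 (0.0414) or 2 (0.0379), with DESeq2 (0.0188) and with no low-count filter (0.0312). Notch2 and Hes1 had changes of -0.09 and -0.20. By edgeR 0 Wnt and 0 Notch genes passed over all genes (6 higher, and 1 higher and 3 lower, unadjusted), and 3 higher, and 1 higher and 2 lower, adjusted over the list alone.

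Metabolic lists shifted slightly. Glycolysis genes had a median of 0.23 over 22 members (camera adjusted p = 0.0353; 0.654 with an estimated correlation; 0.895 without p53+/+ library 2 and 0.13 without p53-/- library 1), and mevalonate genes 0.26 over 23 members (0.00795; 0.548; 0.0658 without p53+/+ library 2 and 0.0523 without p53-/- library 2). The glycolysis median was 0.50 and 0.059 without p53+/+ library 1 and 2 and 0.13 without p53-/- library 1, and the mevalonate median was 0.15 without p53+/+ library 2. DESeq2 called 5 and 2 members higher and 0 lower, over all genes and adjusted over the lists alone, and kept none. By edgeR 0 passed either adjustment, with 5 and 4 higher at an unadjusted p under 0.05. Gapdh and Pkm had changes of 0.32 and 0.44, and Srebf2 and Ldlr of -0.12 and 0.15. Pkm was not called without p53+/+ library 2 (0.303) or p53-/- library 1 (0.359) or 2 (0.807).

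Sex-linked genes separated the libraries otherwise than the genotype. Xist, the RNA of the inactive X chromosome, stood at 587 CPM in p53+/+ library 2 and at 0.0994 to 0.352 CPM in the other 3, where the Y-linked Ddx3y stood at 53.9 to 62.2 CPM against 1 count in p53+/+ library 2. By these genes p53+/+ library 2 held RNA of female mice and the other 3 of male mice, although the labels give no sex. Sex thus differed within the p53+/+ pair, was male in both p53-/- libraries, and is partly mixed with the genotype. The spread behind each p-value includes this difference within the p53+/+ pair. The biological coefficient of variation was 32% for that pair and 22.2% for the p53-/- pair, and how much of it is due to sex was not tested. The list of 8 was not called (camera adjusted p = 0.601, 0.744 with an estimated correlation), and its median of 0.42 and mean of -0.81 differed in sign; DESeq2 called Xist lower (-10.31), over all genes and adjusted over the list alone. That call ended without p53+/+ library 2, where the change was 0.88, and without p53-/- library 1 (0.2) or 2 (0.158). Without p53+/+ library 1 the list passed camera (0.0053). Kdm5c had a change of 0.02. As for edgeR, 0 members passed either adjustment or an unadjusted p under 0.05. Library 2 of p53+/+ also had the lowest Krt19 (247 CPM) and Dmbt1 (689 CPM) and the highest Cd19 (57.3 CPM).

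Over all 28 tested lists, camera called 14 higher and 4 lower at the preset correlation. At an estimated correlation 0 lists passed. That setting had little power, with 2 residual degrees of freedom. The simulated shifted list had a camera p of 5.31e-28 at the preset correlation and 0.00641 at an estimated one. The fibroblast list, all 20 members of which were positive, had an unadjusted camera p of 0.0279 at an estimated correlation. That 0 lists passed therefore does not show that they were unchanged. The directional test of fry called 0, and its mixed test, which asks for change in either direction, called 12.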

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

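No planned scaling, filter or robust fit moved the edgeR counts from 0, and no scaling moved the median of all genes by more than 0.1 on the log2 scale. DESeq2 in place of edgeR gave 1017 higher and 786 lower genes and called Trp53 at -1.32. With an estimated correlation the p53 targets had an adjusted p of 0.548, and 0 lists passed, a setting with little power here, as given above. The DESeq2 counts, whose alternatives were chosen after seeing the data, became 613 higher and 441 lower with the replicate number as a block, 458 and 424 at a change of at least 2-fold, and 579 and 399 at an adjusted p under 0.01. Leaving out 1 library gave 242 to 950 higher and 183 to 538 lower. Of the 1803 calls, 362 were made again without p53-/- library 2, 647 without p53-/- library 1, 664 without p53+/+ library 2 and 879 without p53+/+ library 1, where fewer samples remain. Several changes that edgeR did not call switched sign, and of these DESeq2 called Xist. Upper-quartile scaling gave -0.033 for Spp1 and -0.014 for Kdm5c, the 1 CPM filter -0.00049 for Spp1, and removal of other cell types' genes -0.0017 for Spp1. The replicate block gave -0.047 for Spp1, 0.72 for Dmbt1, 0.58 for Lcn2, 1.01 for Ltf and 0.0022 for Ptprb, and limma-voom -0.045 for Spp1, 0.66 for Dmbt1, 0.54 for Lcn2 and 1.00 for Ltf. DESeq2 turned the sex-linked list lower (0.55). Leaving out 1 library in edgeR gave log2 changes of -0.46 to 0.32 for Spp1, -1.16 to 2.86 for Dmbt1, -0.84 to 2.03 for Lcn2, -1.03 to 0.41 for Ctrb1, -1.75 to 0.20 for Prss2, -0.23 to 0.054 for Mafb, -0.034 to 1.06 for Lyz2, -1.33 to 3.43 for Ltf, -0.74 to 0.18 for Eng, -0.44 to 0.45 for Ptprb and -0.60 to 0.45 for Erbb3. It gave -1.02 to 0.89 for Krt19, -0.056 to 3.03 for Msln, -2.17 to 0.12 for Gpm6a, -0.53 to 0.30 for Klf1, -1.67 to 1.35 for Fcgbp, -0.44 to 2.04 for Vil1, -0.12 to 0.75 for Hbegf, -0.0036 to 0.26 for Ldlr, -11.50 to 0.87 for Xist and -0.21 to 0.30 for Kdm5c. The lists that changed direction had adjusted p of 0.13 to 0.839 (Hippo), 5.84e-06 to 0.772 (ductal), 0.00214 to 0.903 (endocrine), 0.00571 to 0.839 (endothelium), 0.0636 to 0.866 (Schwann) and 1.22e-06 to 0.506 (intestinal). For all these the cause was not tested.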

Other observations

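The tests on fibroblast, macrophage and lymphocyte lists, on genes near Trp53 and on splits of the libraries were set down after the result was seen, as were the genes named; those on dendritic cell markers and clock genes were set before the values of their members were seen, for the clock genes after the kept calls had been seen.

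Several single genes that macrophages express were kept DESeq2 calls, without a list of them being tested. Higher in p53-/- libraries were Gpnmb, a glycoprotein of lipid-laden macrophages (3.52), Trem2, a lipid receptor (1.16), and Msr1, a scavenger receptor (2.00). So were the proteases Ctsd, Ctsb, Ctsl and Lgmn (1.41, 1.09, 1.54 and 1.30), while the lysosomal genes Psap (0.14) and Cd68 (0.36) were not called. Lower were Retnla, a resistin-like protein, at 3040.1 and 3126.7 against 838 and 1268 CPM (-1.55), and the lectins Mgl2 (-1.15), Cd209d (-2.68) and Cd209c (-2.59). Of other markers of the same macrophage state, Mrc1 was called higher (0.59, not kept), Clec10a lay lower in both p53-/- libraries without being called (-0.54), and Cd163 was not called (-0.22).

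Other kept calls higher in p53-/- cells were Igf2bp3, an RNA-binding protein (3.04), Hmga2, a chromatin protein (2.58), and the imprinted gene Mest (2.18). Of 7 tested Reg genes, secreted proteins of the pancreas, 3 were kept: Reg3a (3.0, or 3.75 without p53+/+ library 1), Reg3b (2.96, or 3.76 without it) and Reg2 (2.45). The others, Reg1 (0.50), Reg3d (1.03), Reg3g (1.15) and Reg4 (1.65), were not called.

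Within 5 Mb on either side of Trp53, DESeq2 called 21 of 148 tested genes, 14.2% (exact interval 9% to 20.9%), 19 of them lower, against a median of 10.8% over 894 other windows. That share lay at percentile 74.5 of these windows, whose 95th percentile was 18.4%. A test of this share for variants linked to the Trp53 allele, counting against them under the 75th percentile, was replaced by the clock test after its result was seen. Over all genes 786 of 1803 calls were lower, against 19 of 21 in this window, and directions were not compared between windows. Among the 21 are Per1 and Mgl2 (0.485 and 0.55 Mb away), Nlrp1a, Nlrp1b and Nlrp1c-ps (1.51, 1.57 and 1.66 Mb) and Itgae (3.51 Mb). The mice are B6/129 hybrids, and which strain's sequence each genotype carries near Trp53 was not tested.

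Fibroblast transcripts were higher in p53-/- libraries, with 19 of 20 list members higher in both p53-/- libraries than in both p53+/+ libraries. Without p53+/+ library 2, the one with Xist counts, the list's median was 1.98, which argues against that library setting the difference. Fibroblasts carried through the sort in larger numbers may account for the pattern. A gate on CD133 is meant to remove them, but macrophage transcripts in every library show that it did not remove all other cells. Col3a1 reached 221 and 132 CPM and Sparc 239 and 142 CPM in p53-/- libraries. Expression of these genes by the PanIN cells themselves was not tested and stays open.

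Lymphocyte and dendritic cell transcripts were lower in p53-/- libraries. A smaller immune share as a whole is argued against by the macrophage list, 18 of 20 members of which had a positive change (median 0.42, and 0.28 to 0.72 without 1 library). Type 1 dendritic cell markers not seen before were 12 genes, of which DESeq2 called 8 lower and kept 3. Their median of -1.35 lay at percentile 0.01 of 10000 random lists matched on mean expression, the smallest they can give. Fewer such cells may explain them. The CD133 gate is meant to remove these cells too, but left transcripts of other immune cells. Markers of type 2 and migratory dendritic cells had a median of -0.56, at percentile 0.01 as well. Only Cd209a, Mgl2 and Cd300lg of 10 were called, and the migratory markers Ccr7 (-0.59), Fscn1 (-0.06) and Ccl22 (-0.30) were not. Itgae of the type 1 list and Mgl2 lie near Trp53. Random lists draw genes independently, while markers of 1 cell type move together, so neither percentile measures how often pools of mice differ this much. Without p53+/+ library 2 the lymphocyte list's median was -0.339 and camera still called it (adjusted p = 0.0105, at the preset correlation). The B cell gene Cd22 then stood at 22.5 against 24.9 and 19.2 CPM. Other B-lineage genes stayed lower in that comparison: Igj stood at 78.5 against 6.09 and 9.81 CPM, and Cd19, Cd79a, Ms4a1 and Tnfrsf13c had the changes given above. Whether the larger lymphocyte share of that library or the genotype sets the difference stays open, with 1 other p53+/+ library.

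Some clock output genes were lower in p53-/- libraries: Dbp (-2.29), Tef (-1.15) and Per3 (-1.32) as kept calls, and Per1 (-0.69), which lies near Trp53, as a call that was not kept. Mice sampled at different phases of the clock could give this. The 5 clock genes that peak opposite to Dbp had a median of -0.07, at percentile 40.8 of matched random lists, with Clock called higher (0.40, not kept) and 4 not called, so phase and genotype cannot be told apart by them. A median of 0 or below had been set to count against a difference in phase, and this was met; that it lie below 0 by more than the members' SD was required only after it was seen, because the members went both ways. The 5 tested genes that peak near Dbp had a median of -0.40, at percentile 2.98, with Hlf called lower (-2.48, not kept), Nr1d1 (-1.01), Nr1d2 (-0.24) and Per2 (-0.40) not called and Bhlhe41 at 0.49.

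The 4 libraries can be split in pairs in 3 ways, too few for a share under 0.05. The genotypes gave 1803 DESeq2 calls, and the highest other split gave 44, so 1 of 3 splits gave as many. The other splits mix the genotypes within each group, so any difference between genotypes widens their spread and lowers their counts. At an unadjusted p under 0.05 edgeR counted 241 and 268 genes in them, below the 782 that chance gives. They are therefore no measure of the calls that chance would give.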
